A study of Mus musculus with 16 samples.

How the data were processed

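RNA sequencing of 16 libraries from wild-type mouse fetuses at embryonic day 18.5 was examined: cortex EE and SH, replicates 1 to 5, and hippocampus EE and SH, replicates 1 to 3. Per the labels, RNA was harvested with Trizol and libraries were made with a NEBNext Ultra kit. The authors gave 1 table per library of gene symbols and FPKM values. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR, DESeq2 and the genome build mm10, without the role of each, the annotation, or the filter on genes that were not listed. The tables list 15996 genes in cortex replicates 1 to 3, 15247 in hippocampus and 13448 in cortex replicates 4 and 5, of which 13447 are listed in every cortex library and 13396 in all 16. A gene absent from a table was treated as missing, never as 0. These 3 blocks of libraries were kept apart as the set of replicates within cortex and as the tissue.

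The steps of the FPKM values allowed whole reads to be recovered for 99.78 to 99.85% of genes per block, at a tolerance of 0.003 reads, and the recovery was tested on simulated data. Recovered reads per library ran from 10683140 to 20098661 over genes that hold 84.6 to 87.9% of the summed FPKM, with 362 to 633 reads for the median gene. Summed FPKM was 339726 to 396658 in 15 libraries and 511438 in cortex SH replicate 3. The tables give no fragment totals, so depth is known only as these recovered reads, up to a common factor per block.

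Two-sided tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 1) without further scaling, over genes listed in all libraries of a comparison with a mean FPKM of at least 1, with a Benjamini-Hochberg adjusted p of 0.05 or less as the threshold. This is the branch that the design, fixed before the data were examined, gave for FPKM values. Cortex EE was compared with SH with a term for the set of replicates, and hippocampus EE with SH without covariates. Hippocampus was compared with cortex over replicates 1 to 3 with a term for treatment, and the EE effect was compared between tissues and between cortex sets by interaction terms. Values are means with SD, log2 differences are fitted with their SE, and a direction per library is set against the SH mean of its own block. On simulated data with a log2 shift of 1 put into 67 genes, the cortex test called 80.6% of them and the hippocampus test 53.7%, and at a shift of 0.5 28.4% and 13.4%, with 11 and 9 unshifted genes called.

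A total of 42 gene lists for cell types, pathways and complexes were fixed with the design, and those with at least 5 tested genes were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry with its directional and mixed p. Benjamini-Hochberg adjustment ran over lists. Camera compares a list with the other genes, while fry does not. The named genes were 9 fixed genes of the AHR and Src pathway, the 8 higher and 8 lower genes with the smallest p in each tissue without predicted names, up to 4 members per described list with the smallest p, sex chromosome markers, the 6 higher and 6 lower genes between tissues, and the 5 with the smallest p in each interaction. Some genes that this rule selects are not reported here. Prox1, Nr4a1, Egr3 and Junb in the results, and the genes named under other observations, fall outside this rule and were chosen after their values were seen. Gene positions, types and lengths came from GENCODE M21, with 93.3% of 16250 symbols matched to the gene table. There were 22 symbols turned into dates by a spreadsheet, which are not named, and 1 symbol that stands for 2 genes was left out. Drawings used matplotlib.

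The alternatives set with the design were median-of-ratios scaling, quantile normalization, no filter, a mean FPKM of at least 5, pseudocounts of 0.1 and 0.01, an added log2 threshold of 1, limma without trend but robust, a block for the replicate number, a term for fetal sex, single sets of replicates, all 16 libraries in 1 fit, and leaving out each library. Added after the data were seen were limma-voom on the recovered reads, removal of each library's trend on transcript length, GC content and mean level, leaving out libraries in the comparisons of tissues and of cortex sets, and a fit of 1 EE effect common to all 3 blocks, as were the values of single lists with each library left out, the comparison of all pairings of EE with SH libraries, and swaps of treatment within pairs of equal replicate number. Up to 100 splits of the libraries, the real one among them, were refitted for each count.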

Results

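RNA was sequenced from the cortex and hippocampus of wild-type mouse fetuses at embryonic day 18.5. The series title names the exposure as prenatal. EE stands for an enriched environment, which as background means housing with added space, objects or company, and SH stands for standard habitation. There were 16 libraries: 5 EE and 5 SH from cortex, and 3 EE and 3 SH from hippocampus. Each was given as FPKM, fragments per kilobase of transcript, scaled to the sequenced total. The reads recovered from these values ranged from 14570180 to 19529603 in cortex replicates 1 to 3, from 15307464 to 20098661 in hippocampus, and from 10683140 to 11365260 in cortex replicates 4 and 5. The sample labels name neither fetuses nor litters, so libraries may share a litter, and each p-value measures only the spread between libraries.

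The cortex comparison asked which transcripts differed after prenatal enrichment. Mir124a-1hg, the long noncoding host transcript of the neuronal microRNA miR-124, fell in the EE cortex. Its level was 3.54 ± 1.56 FPKM (SD, n = 5) in EE and 10.7 ± 3.71 FPKM (SD, n = 5) in SH, a log2 difference of -1.38 ± 0.11 (SE). It was lower in 5 of 5 EE libraries (limma, adjusted p = 0.00147), with a log2 difference of -1.39 within replicates 1 to 3 and -1.37 within replicates 4 and 5. The gene is a lincRNA on chromosome 14 of mm10, from 64587331 to 64593961. It was the 1 gene of 12539 tested that passed, with 0 higher and 1 lower, and limma-voom on the recovered reads also called 1. At an unadjusted p under 0.05 there were 934 genes, 245 higher and 689 lower, against 627 by chance.

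Other genes had small p-values without passing, some of them genes of neuronal migration and activity response. Among the genes named here Cxcr4 came next, followed by Cwc22, Zkscan14 and Rprd1b, with Egr1, Txnip and Fos further down. Cxcr4, the receptor of a chemokine that guides migrating neurons and interneurons, measured 10.5 ± 1.498 FPKM in EE and 20.5 ± 2.29 FPKM in SH (SD, n = 5 each; log2 difference -0.90, adjusted p = 0.0728, lower in 5 of 5). The immediate early gene Egr1, on chromosome 18 from 34859823 to 34864984, measured 13.7 ± 1.96 FPKM in EE and 6.34 ± 1.74 FPKM in SH (log2 difference 1.03, adjusted p = 0.185, higher in 5 of 5). Its within-set log2 differences were 1.28 in replicates 1 to 3 and 0.64 in replicates 4 and 5. Fos, another immediate early gene, measured 6.28 ± 1.97 FPKM and 2.89 ± 0.608 FPKM (log2 difference 0.87, adjusted p = 0.314, higher in 5 of 5). Txnip, an inhibitor of thioredoxin that responds to glucose, measured 65.8 ± 11.9 FPKM in EE and 38.9 ± 8.70 FPKM in SH (log2 difference 0.75, adjusted p = 0.271, higher in 5 of 5). Zfp207, Plekhf2, Socs3, Klhl1 and Klf4 had log2 differences from 0.36 to 0.55, and Cwc22, Zkscan14, Rprd1b, Zfp105 and Tsku from -0.70 to -0.50. Their adjusted p-values ran from 0.163 to 0.323, and each held its direction in 5 of 5 EE libraries.

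The call for Mir124a-1hg was lost when replicates 1 to 3 were fitted alone or when the term for the set of replicates was left out, with 0 genes each, while replicates 4 and 5 alone gave 435 genes from 2 libraries per treatment. SH replicate 3 stood apart from the other cortex libraries, and without it 3 genes passed: Mir124a-1hg, Cxcr4 at a log2 difference of -0.83 and Rprd1b at -0.79.

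**Figure D1:**
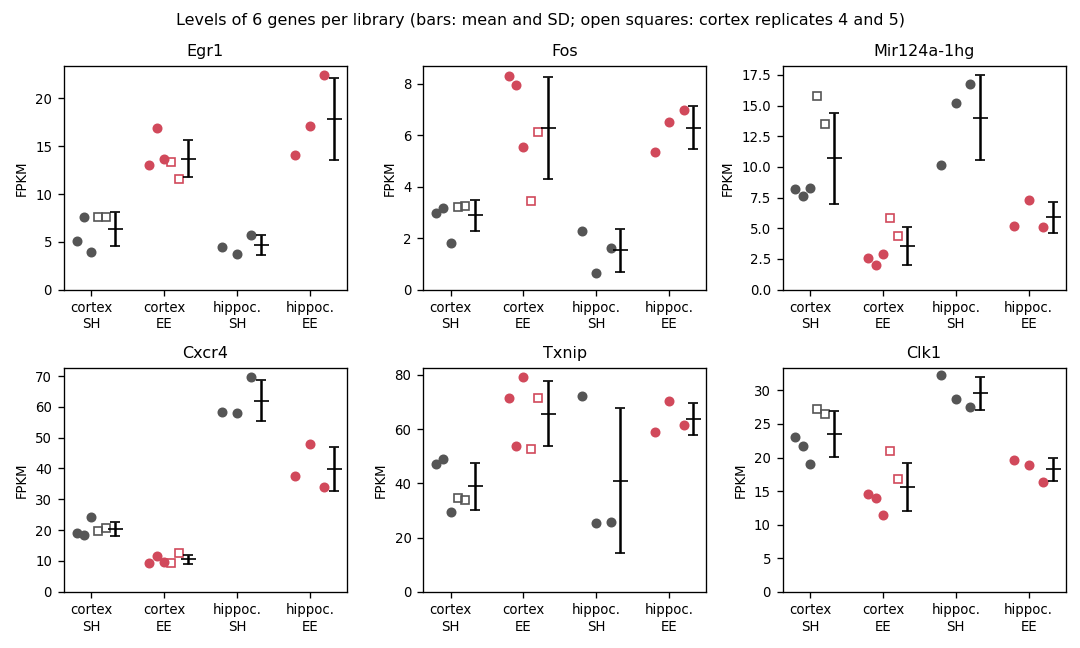
FPKM (vertical axes) of 6 genes in each library of cortex and hippocampus, SH in grey and EE in red, with the mean and SD beside the points and cortex replicates 4 and 5 as open squares. Egr1 averaged 13.7 FPKM in EE and 6.34 FPKM in SH cortex, and Mir124a-1hg 3.54 and 10.7 FPKM; of the 6 genes only Mir124a-1hg passed, in cortex.

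Among the immediate early genes of cortex, members moved both ways. None of the 16 tested members passed over all genes, and 5 passed when adjusted over the list alone, 4 higher and 1 lower. Egr1, Fos and Klf4, a transcription factor induced by stimuli in many cells, were among those higher. Arc, which encodes a synaptic plasticity protein, was the lower one at 1.37 ± 0.416 FPKM in EE and 2.39 ± 0.266 FPKM in SH (SD, n = 5 each; log2 difference -0.53). Nr4a1, Egr3 and Junb, immediate early genes of the same list, had log2 differences of -0.09, -0.16 and -0.02. The list did not pass the directional test of camera (adjusted p = 0.0899, and 0.795 with an estimated correlation), while the mixed test of fry, which asks whether members change in either direction, gave an adjusted p of 5.85e-05.

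Cell-cycle, interferon and mural-cell genes were lower in the EE cortex as lists tested with a preset correlation between genes, but none of these lists passed with an estimated correlation (adjusted p = 0.795 each). Of the S phase genes 15 of 19 were negative (median log2 difference -0.19, camera adjusted p = 0.0109), with Mcm7, a helicase subunit of DNA replication, at 28.3 ± 1.73 FPKM in EE and 33.7 ± 1.38 FPKM in SH. Of the G2 and M phase genes 17 of 22 were negative (median -0.09, adjusted p = 0.0491), and the mitotic kinase Aurka, at 3.30 ± 0.573 and 4.82 ± 0.305 FPKM, was the 1 gene that passed when adjusted over the list alone. Of the interferon response genes 12 of 14 were negative (median -0.28, adjusted p = 0.00169), with the ubiquitin-like Isg15 at 2.61 ± 1.05 FPKM in EE and 4.08 ± 1.15 FPKM in SH. Among pericyte and smooth muscle genes 9 of 13 were negative (median -0.12, adjusted p = 0.0279), and 4 passed when adjusted over the list alone, namely the contractile genes Myl9 (log2 difference -0.57), Tagln (-0.61) and Acta2 (-0.46), and Ndufa4l2 (-0.49). The meninges and fibroblast list did not pass, with 17 of 19 genes negative (median -0.15, adjusted p = 0.123), but it did without EE replicate 5 (7.66e-05) or SH replicate 2 (0.0221), and its median was -0.02 without EE replicate 4. In the other direction, 11 of 12 transcripts of the mitochondrial genome were positive (median 0.16, adjusted p = 0.0369), with ND2, a subunit of respiratory complex I, at 2587 ± 259 FPKM in EE and 2118 ± 350 FPKM in SH. Its adjusted p with an estimated correlation was 0.795 as well. Each of these 5 lists kept its direction and passed with SH replicate 3 left out, and 0 of their genes passed over all genes. With other libraries left out the interferon list passed each time, while without EE replicate 4 the S phase, G2 and M, pericyte and mitochondrial lists had adjusted p-values of 0.0723, 0.553, 0.179 and 0.290. The G2 and M list was also lost without EE replicate 3 (adjusted p = 0.371), without SH replicate 1, 2, 4 or 5 (0.244, 0.0693, 0.0599 and 0.0568) and with the trend on length and GC content removed (0.114), and the mitochondrial list without EE replicate 1 (0.0563) or SH replicate 2 or 4 (0.0547 and 0.207). With that trend removed the G2 and M median was -0.07, close to the -0.09 before. The interferon, S phase and pericyte lists then had 0.0472 each, with medians of -0.23, -0.13 and -0.10. The interferon median was -0.19 without EE replicate 4 and -0.43 without EE replicate 5, the pericyte median -0.21 and -0.19 without SH replicates 1 and 3, and the G2 and M median -0.02 without EE replicate 3 or SH replicate 1, -0.06 without EE replicate 4 and -0.14, -0.19 and -0.18 without EE replicate 1, EE replicate 5 and SH replicate 3.

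Synaptic genes were higher and ribosomal protein genes lower in the EE cortex as lists tested with the preset correlation, and both moved with SH replicate 3. With an estimated correlation none of these 5 lists passed (adjusted p = 0.795 each), and 0 of their genes passed over all genes or adjusted over the list alone. Of 20 glutamate receptor genes 19 were positive (median 0.18, adjusted p = 0.00084), of 16 genes of GABA receptors and chloride transporters 15 (median 0.20, adjusted p = 0.00124), of 24 presynaptic genes 19 (median 0.13, adjusted p = 0.00815) and of 21 postsynaptic genes 17 (median 0.17, adjusted p = 0.0115). Grm2, a presynaptic metabotropic glutamate receptor, measured 7.55 ± 1.62 FPKM in EE and 5.75 ± 1.36 FPKM in SH, and Shank3, a scaffold of excitatory synapses, 11.6 ± 1.29 and 8.37 ± 2.33 FPKM (SD, n = 5 each). Of 45 genes of cytosolic ribosomal proteins 44 were negative (median -0.25, adjusted p = 0.00501). In SH replicate 3 the mean log2 level was 2.45 for the glutamate receptor genes, against 3.15 to 3.29 in the other SH libraries, and 9.38 for the ribosomal protein genes, against 8.01 to 8.26. Without that library the glutamate, GABA, presynaptic and postsynaptic lists had medians of 0.05, 0.08, 0.05 and 0.02 and adjusted p-values of 0.085, 0.0535, 0.0998 and 0.634, and the ribosomal median was 0.01 with an adjusted p of 0.327. Within the sets the ribosomal median was -0.67 in replicates 1 to 3 and 0.36 in replicates 4 and 5, and the postsynaptic median was 0.35 and -0.10. The Spearman rho between a library's deviation from its block and transcript length also separated EE from SH in each set. It was 0.444 to 0.644 in EE and -0.761 to 0.275 in SH of replicates 1 to 3. In replicates 4 and 5 it was -0.361 to -0.244 in EE and 0.272 to 0.459 in SH. The length trend thus turned between the sets, as these medians did. The ribosomal and postsynaptic lists were also lost without EE replicate 1 (0.145 and 0.0677) and without EE replicate 2 (0.0714 each). The ribosomal median was -0.16 without EE replicate 1 and -0.44 without EE replicate 5, the GABA median 0.30 without EE replicate 5, and the presynaptic median 0.19 and 0.20 without EE replicate 5 and SH replicate 5. With the trend on length and GC content removed the glutamate, GABA and ribosomal lists passed at 0.0131, 0.0136 and 0.0472, and the presynaptic and postsynaptic lists were at 0.0509 and 0.118. The ribosomal median was then -0.08, against -0.25 before, and the presynaptic and postsynaptic medians were 0.07 and 0.06. The glutamate and GABA medians were 0.15 each. In all, 10 of 41 lists passed, 5 higher and 5 lower, 0 with an estimated correlation and 0 by the directional test of fry, whose smallest adjusted p was 0.602. Without SH replicate 3, 7 lists passed, 5 of them shared, and without EE replicate 5, 17 passed. Those added without SH replicate 3 were choroid plexus and ependyma genes (median 0.31, adjusted p = 0.0171, and 0.0980 with it) and striatal genes (median -0.13, adjusted p = 0.0215, and 0.0899 with it), each at 0.932 with an estimated correlation. The choroid plexus list also passed without EE replicate 3 (median 0.32, adjusted p = 0.0191), while its median was 0.02 without EE replicate 4 (adjusted p = 0.694) and 0.09 without SH replicate 2 (0.293). The striatal list also passed without EE replicate 3 (median -0.09, adjusted p = 0.0255) and EE replicate 4 (-0.17, 0.00452). Of the striatal genes 12 of 16 were negative with all libraries, and the dopamine receptor Drd1 was the 1 of them that passed when adjusted over the list alone (log2 difference -0.69).

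The hippocampus comparison asked the same question in 3 EE and 3 SH libraries. No gene of 13344 passed in limma, with 0 by limma-voom as well and 503 genes at an unadjusted p under 0.05, 94 higher and 409 lower, against 667 by chance. Egr1 had the smallest p, at 17.9 ± 4.26 FPKM in EE and 4.67 ± 1.02 FPKM in SH (SD, n = 3 each; log2 difference 1.73, adjusted p = 0.633, higher in 3 of 3). Fos, on chromosome 12 from 85473890 to 85477273, measured 6.28 ± 0.835 and 1.52 ± 0.831 FPKM (log2 difference 1.58, higher in 3 of 3). Clk1, a kinase of splicing factors, measured 18.3 ± 1.73 and 29.6 ± 2.45 FPKM (log2 difference -0.67), and Mir124a-1hg 5.89 ± 1.24 and 14.0 ± 3.45 FPKM (log2 difference -1.11), both lower in 3 of 3. Dynlt1c and Dynll1, light chains of dynein, had log2 differences of 0.46 and 0.32. The small RNA genes Mir7-1, Snora52 and Snora81 had 0.72 to 0.85, from short features that can share reads with their host genes. The zinc finger genes Zfp719, Zfp87, Zfp418 and Zfp37, and Kbtbd7, had -1.08 to -0.55, each lower in 3 of 3. Adjusted p was 0.9996 for all of the genes named here except Egr1.

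Immediate early, ribosomal, respiratory and microglial genes were higher in the EE hippocampus as lists tested with the preset correlation, and neurogenic and mitotic genes lower. With an estimated correlation none of these lists passed (adjusted p = 0.672 for the immediate early list and 0.999 for the other 5). Of 16 immediate early genes 10 were positive (median 0.17, camera adjusted p = 0.00259). Egr1 and Fos were the 2 that passed when adjusted over the list alone, beside 0 over all genes. Of 15 genes of intermediate progenitors and newborn neurons 14 were negative (median -0.22, adjusted p = 0.00928), with Neurog2, a proneural factor of excitatory neurons, at 8.73 ± 1.98 FPKM in EE and 14.0 ± 1.24 FPKM in SH, and Eomes, a marker of intermediate progenitors, at 23.0 ± 3.64 and 28.1 ± 4.44 FPKM (SD, n = 3 each). All 22 of 22 genes of G2 and M phase were negative (median -0.22, adjusted p = 0.00928), with Aurka at 6.63 ± 1.34 and 8.77 ± 2.13 FPKM. All 18 of 18 microglia and macrophage genes were positive (median 0.21, adjusted p = 0.00928), with the adaptor Tyrobp at 23.6 ± 2.94 FPKM in EE and 19.0 ± 8.47 FPKM in SH. Of the cytosolic ribosomal protein genes 42 of 45 were positive (median 0.15, adjusted p = 2.59e-09), and of the oxidative phosphorylation genes 37 of 38 (median 0.14, adjusted p = 1.46e-08). Of the lists other than the immediate early one, 0 genes passed over all genes or adjusted over the list alone. The ribosomal and respiratory lists passed with each library left out, with medians of 0.07 each without EE replicate 1 or SH replicate 2, and of 0.24 and 0.22 without EE replicate 2. The ribosomal and respiratory lists moved with a length trend: in EE replicate 1 the deviation from the hippocampal mean had a Spearman rho across genes of -0.483 with transcript length, against -0.141 to 0.232 in the other hippocampal libraries. With the trend on length and GC content removed, a setting chosen after the data were seen, their adjusted p-values were 0.485 and 0.719. The microglial list was lost without EE replicate 2 (adjusted p = 0.180), and without SH replicate 2 its median was -0.10 (adjusted p = 0.336), while it was 0.35 without EE replicate 1 and 0.56 without SH replicate 1. The lists of meninges and choroid plexus, which did not pass (medians 0.23 and 0.80, adjusted p = 0.0671 and 0.0725), had medians of -0.31 and -0.12 without SH replicate 2 and of 0.01 and 0.08 without EE replicate 2. The meninges list passed without EE replicate 1 (median 0.53, adjusted p = 1.22e-06), SH replicate 1 (0.63, 2.67e-05) or SH replicate 3 (0.23, 0.0413), and the choroid plexus list without EE replicate 3 (1.67, 0.000215) or SH replicate 1 (2.06, 8.76e-08), with medians of 0.48 and 0.28 without EE replicate 1 and SH replicate 3. The G2 and M list was lost without EE replicate 3 or SH replicate 1 (medians -0.06 and -0.03, adjusted p = 0.4998 and 0.859) and had a median of -0.36 without SH replicate 2. The list of intermediate progenitors was lost without EE replicate 3 (median -0.13, adjusted p = 0.327) and the immediate early list without SH replicate 1 (adjusted p = 0.0585), with a median of 0.10 without EE replicate 3. In all, 6 of 42 lists passed, 4 higher and 2 lower, 0 with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.175. Without EE replicate 2, 10 lists passed, and without SH replicate 1, 2 or 3 there were 14, 12 and 11.

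**Figure D2:**
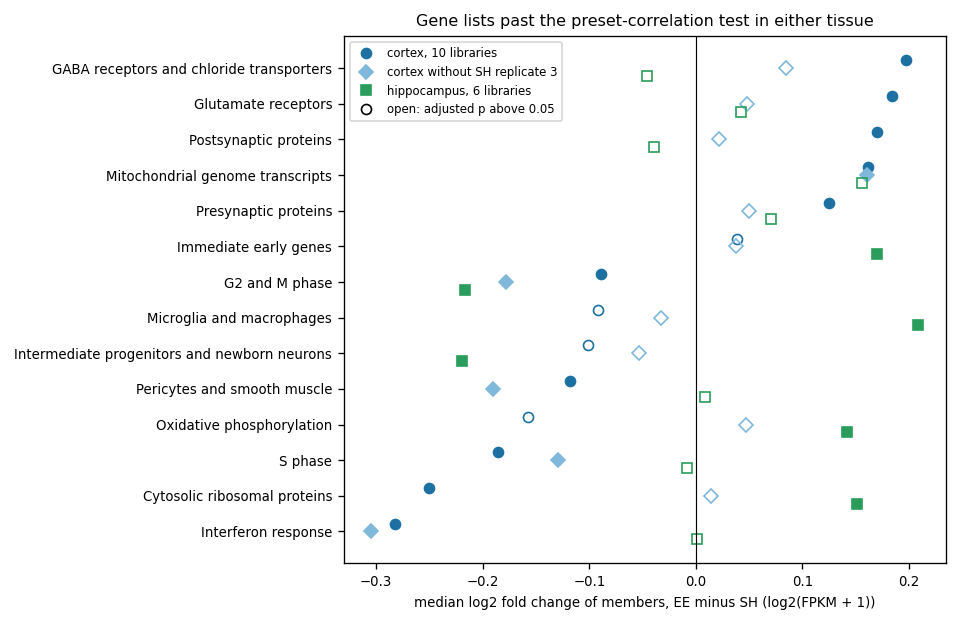
Median log2 difference, EE minus SH (horizontal axis), of each gene list past the preset-correlation test in either tissue, for cortex with 10 libraries (circles), cortex without SH replicate 3 (diamonds) and hippocampus with 6 libraries (squares), filled where the adjusted p was 0.05 or less. The ribosomal median was -0.25 in cortex, 0.01 without SH replicate 3 and 0.15 in hippocampus, and no list passed with an estimated correlation.

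The series title names the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, and the tyrosine kinase Src. Neither transcript passed in either tissue. Src measured 28.9 ± 2.29 FPKM in EE and 29.1 ± 2.96 FPKM in SH cortex (SD, n = 5 each; log2 difference -0.01, 95% interval -0.23 to 0.21, adjusted p = 0.990, lower in 2 of 5). In hippocampus it measured 26.9 ± 1.73 and 28.2 ± 3.83 FPKM (n = 3 each; log2 difference -0.06, 95% interval -0.34 to 0.21, lower in 3 of 3). Ahr measured 0.955 ± 0.118 and 1.11 ± 0.288 FPKM in cortex (log2 difference -0.11, 95% interval -0.31 to 0.10) and 1.13 ± 0.142 and 1.34 ± 0.105 FPKM in hippocampus (log2 difference -0.13, 95% interval -0.46 to 0.20). At levels near 1 FPKM the scale of log2(FPKM + 1) shrinks a fold change, so these intervals do not bound the fold change of Ahr itself. The AHR targets Cyp1b1, Tiparp and Nqo1 had log2 differences of 0.18, -0.14 and -0.07 in cortex and -0.21, -0.21 and 0.40 in hippocampus. The AHR partner Arnt had 0.03 and -0.18, and the Src family kinase Fyn 0.08 and -0.11. Leaving out 1 library changed the sign of some of these small values. Nqo1 was 0.05 in cortex without SH replicate 3 and -0.40 in hippocampus without SH replicate 2. Cyp1b1 was 0.01 in hippocampus without SH replicate 1. Tiparp in both tissues and Cyp1b1 in cortex kept their sign. The AHR repressor Ahrr measured 0.602 and 0.537 FPKM in EE and SH cortex, under the filter, and had a log2 difference of -0.13 in hippocampus. Cyp1a1, the classical AHR target, is not analysed here because no library lists it. As lists, the AHR pathway genes had adjusted p-values of 0.764 in cortex (10 genes, 6 negative) and 0.800 in hippocampus (13 genes, 8 negative), and the Src family and partner genes 0.268 (22 genes, 12 positive) and 0.259 (22 genes, 14 negative). Genes of neuronal maturation had adjusted p-values of 0.268 in cortex, where 11 of 18 were positive, and 0.118 in hippocampus, where 13 of 18 were positive. In cortex the microtubule genes Map2 and Dcx had log2 differences of 0.38 each, and 0.16 and 0.14 without SH replicate 3.

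The comparison of hippocampus with cortex tested whether the libraries carry the tissue of their titles, over replicates 1 to 3. Hippocampal patterning genes were higher in hippocampus and striatal genes lower. Of 18 hippocampal regional markers 13 rose and 3 fell, among them Emx2, a patterning factor of the medial pallium, at 20.4 ± 2.62 FPKM against 4.81 ± 0.232 FPKM in cortex (SD, n = 6 each; log2 difference 1.87, adjusted p = 1.6e-07, higher in 6 of 6), and Prox1, a factor of dentate granule cells, at 12.2 ± 5.22 and 2.42 ± 0.548 FPKM. Of 16 striatal genes 13 were lower and 0 higher in hippocampus, including the tachykinin precursor Tac1, at 1.22 ± 0.598 against 21.3 ± 4.85 FPKM, and the adenosine receptor Adora2a, at 1.31 ± 0.19 against 8.40 ± 1.47 FPKM. Progenitor and mitotic genes were higher in hippocampus, with 12 of 15 genes of intermediate progenitors and newborn neurons and 21 of 22 of G2 and M phase past the threshold. Presynaptic genes were lower, with 16 of 24 past it. Lhx2, Col2a1, Dmrta2, Ltbp1 and Thrsp also rose, by log2 differences of 1.47 to 2.80, and Scg2, Dclk3, Stac and Cpne6 had -2.94 to -1.63. In all, 4661 of 13158 genes passed, 3233 higher and 1428 lower in hippocampus. The median of all genes was 0.09, and with median-of-ratios scaling, which moved it to -0.03, 4390 passed, 2158 higher and 2232 lower.

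The difference between the EE effects of the 2 tissues was tested gene by gene over replicates 1 to 3. No gene of 13158 passed in limma, with 990 at an unadjusted p under 0.05 against 658 by chance. The smallest adjusted p, 0.495, was shared by Tmem86b, Tradd, Prss36, Rps6 and Supt4b, the last annotated as a processed pseudogene. As lists, 11 of 42 differed between the tissues and 0 with an estimated correlation (adjusted p = 0.961). The ribosomal protein genes had the smallest adjusted p (3.68e-16), with a median of 0.80 for hippocampus minus cortex and 45 of 45 positive, and the median was 0.45 without cortex SH replicate 3. The oxidative phosphorylation genes had a median of 0.75, and 0.40 without that library. The Src family and partner genes had a median of -0.23, and -0.07 without it. Without it 8 lists differed, all 8 among the 11. Cortex replicates 4 and 5 are not in this test. Their ribosomal and oxidative phosphorylation medians of the EE effect were 0.36 and 0.40, above the 0.15 and 0.14 of hippocampus. The order of these lists between the tissues thus depended on the set of cortex replicates.

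The EE effect was compared between cortex replicates 1 to 3 and 4 to 5. No gene of 12539 passed in limma, with 2434 at an unadjusted p under 0.05 against 627 by chance, and the smallest adjusted p was 0.251. The genes with the smallest p were Mus81, a nuclease of DNA repair, Olig1 and Id1, transcription factors of glia and progenitors, and Vkorc1 and Lsm10, with differences of 1.04 to 1.69 on the log2 scale. Without SH replicate 3, 3 genes passed, and without EE replicate 5, 1 gene. Across genes, which are not independent replicates, the log2 differences of the sets had a Pearson r of -0.404 and a Spearman rho of -0.400, and r was -0.116 without SH replicate 3 and -0.283 without EE replicate 5. Of 60 relabellings within the sets 18 gave an r as large in size. Between cortex and hippocampus r was 0.194 and rho 0.138 over 12314 genes, with an r of -0.236 for cortex replicates 1 to 3 and 0.605 for replicates 4 and 5. It was 0.573 without SH replicate 3 and 0.0243 and 0.0281 without EE or SH replicate 4.

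**Figure D3:**
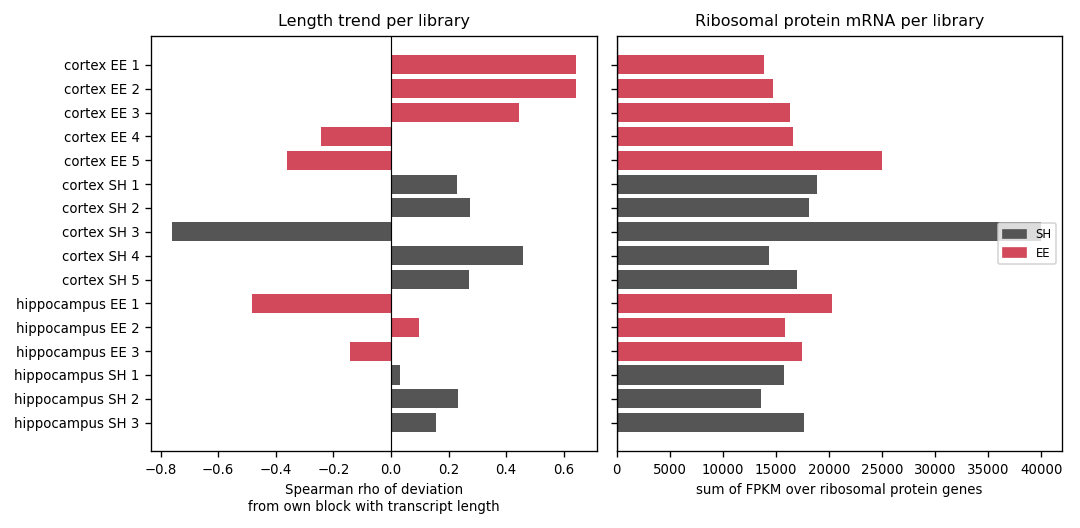
Spearman rho across genes between each library's deviation from its own block (cortex 1 to 3, cortex 4 to 5 or hippocampus) and transcript length (left), and summed FPKM of cytosolic ribosomal protein genes (right), with 1 bar per library, EE in red and SH in grey. Cortex SH replicate 3 had the lowest rho, -0.761, and the highest sum, 39956 FPKM.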

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

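Of the tests below, those on erythroid genes and on choroid plexus genes were chosen only after the results were seen, as were the EE effect common to both tissues, the lists of the interaction test without cortex SH replicate 3, the counts of single hippocampal splits and the swaps within pairs, and the others before.

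In cortex SH replicate 3 many values lay far from those of the other SH libraries. The Spearman rho across genes between its deviation from its block and transcript length was -0.761 (others 0.231 to 0.459), the SD of that deviation 0.639 (others 0.154 to 0.292), the summed FPKM of ribosomal protein genes 39956 (others 14345 to 18880), that of globin genes 3827 (others 808 to 1540), and its median correlation with the other cortex libraries 0.943 (others 0.9752 to 0.9876). Its mean log2(FPKM + 1) was 4.89 for presynaptic genes (others 5.34 to 5.41), 3.11 for postsynaptic genes (others 3.85 to 4.05), 2.45 for glutamate receptors (others 3.15 to 3.29), 2.93 for GABA receptors and chloride transporters (others 3.52 to 3.72) and 9.38 for ribosomal proteins (others 8.01 to 8.26), and Fos was at 1.495 (others 1.99 to 2.09). Among EE libraries of cortex, replicate 5 had a ribosomal sum of 25002 FPKM (others 13846 to 16617) and Fyn at 5.69 (others 5.90 to 5.92), and replicate 4 had Zfp207 at 4.99 (others 4.53 to 4.62) and a median correlation of 0.978 (others 0.984 to 0.985). A gap this wide was found in 15 of 82 groups of 5 libraries, 11 of them for SH replicate 3. Chance gives about 1 in 20 for independent groups. These groups overlapped, as for ribosomal genes, and included genes and lists picked by the cortex test on the same libraries. The counts can therefore not be judged against that rate.

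For SH replicate 3, hippocampal tissue was the only other region tested. A score of 20 hippocampal minus 20 cortical genes was -1.51, within the -1.69 to -1.44 of the other cortex libraries and far from the hippocampal mean of 2.41. Its genes had the smallest p in the tissue comparison, where this library itself counted as cortex. The score thus leans towards cortex and cannot exclude hippocampal tissue. Blood in the library is argued against as the source by the erythroid genes other than globins: their median ratio to SH replicates 1 and 2 was 1.16 over 3 listed genes, with Alas2 at 1.87, while Hba-a1 was at 2.50 and Hbb-bs at 3.95. A recovery of RNA that depends on transcript length stays open too. Against the other SH libraries of its block, the rho of its deviation with length was -0.747, outside the -0.359 to 0.694 of the other 5 libraries, so lower recovery of long transcripts may account for the lower synaptic and higher ribosomal values in this library. No biological explanation was tested, since the labels give none for a single library.

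In the interaction test, 11 lists differed between the EE effects of hippocampus and cortex over replicates 1 to 3. The adjusted p was 3.68e-16 for ribosomal proteins, 4.70e-13 for oxidative phosphorylation, 1.44e-05 for axon guidance, 1.84e-05 for postsynaptic proteins, 0.00223 for GABA receptors and chloride transporters, 0.00347 for microglia and macrophages, 0.00687 for glutamate receptors, 0.0169 for Src family kinases and partners, and 0.0287 each for retinoic acid signalling, interferon response and erythroid cells. Over replicates 1 to 3, ribosomal, respiratory, microglial, retinoic acid, interferon and erythroid genes had the higher EE effect in hippocampus, and the other 5 lists the higher one in cortex. In cortex replicates 4 and 5, outside this test, the ribosomal and respiratory medians were 0.36 and 0.40, against 0.15 and 0.14 in hippocampus. The axon guidance, postsynaptic, glutamate receptor and Src medians there were lower than in hippocampus, so their order turned too. The GABA, microglial, retinoic acid, interferon and erythroid lists kept their order. With an estimated correlation none differed (adjusted p = 0.961), and glutamate receptors, retinoic acid signalling and erythroid cells were lost without cortex SH replicate 3, with adjusted p-values of 0.0775, 0.0737 and 0.150.

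Between the hippocampal libraries Ttr, which encodes the main secreted protein of the choroid plexus, measured 4989, 10300 and 33.6 FPKM in EE replicates 1 to 3 and 16656, 37.9 and 144 FPKM in SH replicates 1 to 3. Of 13 other choroid plexus and ependyma genes 12, or 92.3%, were highest in SH replicate 1, where Ttr was highest, so choroid plexus tissue taken with some hippocampi may account for the spread. The list had an adjusted p of 0.0725 in hippocampus, with 14 of 14 genes positive and 6 genes also tested in cortex, and 0.999 with an estimated correlation. Nqo1 measured 24.8 FPKM in SH replicate 1 and 0.901 FPKM in SH replicate 2, so its value in hippocampus was measured in libraries that differ in choroid plexus genes. A biological difference in choroid plexus between the groups was not tested and stays open.

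Other splits of the libraries were refitted beside each count, and the real split is included in each number of splits given. For the cortex gene count a share under 0.05 of the splits was as large (1 gene, at most 1 in the other splits, 2 of 100). The share was also under 0.05 for the tissue count (4661 genes, at most 0 in the others, 1 of 100). So it was for the EE effect common to both tissues (42 genes, at most 0 in the other relabellings, 1 of 100 out of 1200 possible). Another cortex split thus matched the real count of 1 gene, and the cortex splits were not kept within the sets of replicates. Libraries may share litters or fetuses, and the splits treat them as independent, so these shares do not exclude chance for the EE counts. Chance was not excluded for the cortex lists (10 lists, at most 20, 43 of 100 as large). For the difference between tissues the real count was 0 genes, which no relabelling can fall below, so the 100 relabellings decide nothing; the highest gave 45 genes, a structure of the libraries that was not traced. In hippocampus the 10 splits are too few for a share under 0.05. The real counts were 0 genes and 6 lists, and the highest others 110 genes and 23 lists. The real split gave the fewest lists of the 10, with a median of 14 in the others. The number of hippocampal lists thus did not set EE and SH apart from other groupings. The split with 110 genes set EE replicates 1 and 2 and SH replicate 1, which had 4989 FPKM of Ttr or more, against the other 3 libraries, so it points to a structure that follows the choroid plexus genes. With replicate numbers as blocks and treatment swapped within pairs of equal number, the 16 assignments in cortex and 4 in hippocampus are too few as well. Cortex had 1 gene and 13 lists, against at most 0 and 21 in the others, and hippocampus 11 lists, against at most 26. As many lists were found in 5 of the 16 in cortex and in all 4 in hippocampus, the real ones included. The medians of the others were 9 and 20 lists.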

How the results depend on the processing

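The removal of length and GC trends, limma-voom, the fit of a common EE effect and leaving out libraries between tissues and between sets were chosen only after the data were seen; the other settings were planned. The cause of each change was not tested, except where fewer genes or libraries were in the fit. For cortex, the call of Mir124a-1hg was shared by every setting except the fits without the set term and with replicates 1 to 3 alone, which called 0 genes, and counts moved to 3 with quantile normalization, 2 with an unadjusted p and a log2 difference of 1, 6 with length and GC trends removed, 10 with all 16 libraries in 1 fit and 435 with replicates 4 and 5 alone. Leaving out each library gave 1 to 3 genes in cortex, 0 to 3 for the difference between cortex sets, 17 to 228 for the common effect, 3662 to 5760 between tissues, and 0 throughout for hippocampus and for the difference between tissues. With an unadjusted p and a log2 difference of 1 there were 4 genes in hippocampus, 599 between tissues, 86 for the difference between tissues and 576 for the difference between sets, and tissue counts were 2744 with a mean FPKM of at least 5 and 583 with a log2 difference of 1. Cortex lists numbered 0 with an estimated correlation or by the directional test of fry, 1 by its mixed test, 6 with length and GC trends removed and 5 with replicates 4 and 5 alone. Hippocampus lists numbered 0 with an estimated correlation or by either test of fry. With the replicate number as a block they numbered 11, the cortex lists 13 and the common effect 25 genes. After each group's mean was taken out, 9 of 10 cortex libraries correlated best with the library of their own number in the other treatment, where the 4 libraries of replicates 4 and 5 give a single outcome, and of 12 pairings within the sets the one by equal numbers had the highest mean correlation (0.233, next 0.196). In hippocampus 4 of 6 pairings had one as high (-0.0693 by equal numbers). Leaving out each library gave 7 to 17 lists in cortex and 8 to 14 in hippocampus. The common effect held 102 genes with length and GC trends removed. The correlation of EE effects between cortex sets was -0.0846 with length and GC trends removed and -0.449 to -0.116 over left-out libraries, and that between tissues was 0.390 with the trends removed, 0.0243 to 0.573 over left-out libraries, and reversed to -0.236 with cortex replicates 1 to 3 alone. Named genes kept direction and side of the threshold in 1932 of their values under other settings, came to pass it in 8 and reversed in 19, none of the reversed ones past the threshold. Mir124a-1hg in cortex kept its call in the 17 settings of this tally. The fits that lost it, without the set term and with replicates 1 to 3 alone, are not among them. Over left-out libraries the log2 difference in cortex ran from -0.122 to 0.135 for Arnt, -0.156 to 0.0454 for Nqo1 and -0.0720 to 0.0489 for Src, and in hippocampus from -0.498 to 0.0116 for Cyp1b1, -0.401 to 1.48 for Nqo1, -0.125 to 0.0440 for Src and -0.0893 to 0.679 for C1qc. Src in cortex was at 0.00174 with median-of-ratios scaling and 0.00483 by limma-voom, and with length and GC trends removed Nqo1 in cortex was at 0.0624 and Ndufa8 and Ndufb10 in hippocampus at -0.00474 and -0.00358. What depth limits was not separated from the spread between libraries: on simulated data a log2 shift of 0.5 was called for 28.4% of genes in cortex and 13.4% in hippocampus.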

Other observations

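The fit of 1 EE effect over all 3 blocks, the class of zinc finger genes, the test without cortex SH replicate 3 and the reading of nuclear RNA by tissue were chosen only after results were seen, while the tests on length and GC content and short-lived mRNAs were set before their results.

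Read over both tissues, EE libraries shared a small set of genes. With 1 EE effect fitted over cortex replicates 1 to 3, cortex replicates 4 and 5 and hippocampus, 42 of 12672 genes passed in limma, 4 higher and 38 lower, and each of those described here held its direction in 8 of 8 EE libraries. Egr1 (log2 difference 1.29 ± 0.16 SE, adjusted p = 0.00125) and Fos (1.14 ± 0.18, adjusted p = 0.0135), both immediate early genes, rose, as did the splicing factor Tra2a (0.44 ± 0.09, adjusted p = 0.0429). Mir124a-1hg (-1.28 ± 0.11, adjusted p = 4.51e-05), the chemokine receptor Cxcr4 (-0.80 ± 0.10, adjusted p = 0.00125), the splicing kinase Clk1 (-0.61 ± 0.07, adjusted p = 0.00125) and the dopamine receptor Drd1 (-0.58 ± 0.11, adjusted p = 0.0299) fell. Drd1 belongs to the list of striatal genes, of which 12 of 16 were negative in cortex and 8 of 11 in hippocampus (medians -0.09 and -0.10), and a difference in striatal tissue between the EE and SH dissections was not tested. Libraries of both tissues may share fetuses, and with the replicate number as a block 25 genes passed, 23 of them among the 42. Leaving out cortex EE replicate 3, 4 or 5, cortex SH replicate 1, 4 or 5, hippocampus EE replicate 1 or 3 or hippocampus SH replicate 3 gave 17 to 25 genes. By limma-voom 30 passed, all 30 of them shared, and without cortex SH replicate 3 228 passed, with all 42 among them.

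Genes with names in Zfp, which encode zinc finger proteins and many of which repress transcription, were lower as a class in EE. Their median log2 difference was -0.13 over 309 genes in cortex, with 73.8% negative, and -0.21 over 319 genes in hippocampus, with 86.5% negative. For all genes the medians were -0.02 and -0.01, with 54.0% and 52.8% negative. Within cortex the median of the class was -0.05 in replicates 1 to 3, -0.13 in those without SH replicate 3, and -0.36 in replicates 4 and 5. The medians of all genes were -0.03, -0.05 and -0.01 there. In replicates 1 to 3, 56.8% of the class were negative, close to the 53.3% of all genes. Median-of-ratios and quantile scaling kept the sign in both tissues. In the common fit 10 of the 42 genes, or 23.8%, were of this class, against 2.46% of tested genes, all 10 lower, among them Zfp719 at -0.92 and Zfp87 at -0.67.

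For the zinc finger genes, cortex SH replicate 3 is argued against as the source, since without it their median lay -0.21 from that of all genes. In replicates 1 to 3 the class median was -0.05 with it and -0.13 without it. No other library was left out for this class, so another single library was not tested as the source. A trend on length and GC content is argued against as the whole cause, since the median residual was -0.15 in cortex without SH replicate 3 and -0.148 in hippocampus. Less nuclear RNA in EE libraries is argued against in hippocampus by nuclear-enriched long noncoding RNAs, whose median was 0.138 over 12 genes (quartiles 0.0450 and 0.171), and stays open in cortex, where it was 0.119 over 10 genes, 0.0283 without SH replicate 3 and -0.116 in replicates 1 to 3 without that library. Lower levels of short-lived mRNAs in general remain open, because other short-lived mRNAs lay 0.00914 above the median of all genes in cortex, but had a median of -0.0837 against -0.0226 for all genes without SH replicate 3, and of -0.0693 against -0.0105 in hippocampus. An effect of EE on this class stays open too, as a hypothesis found and examined on the same libraries.

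Sex chromosome genes differed between libraries of the same number. Xist, which silences an X chromosome in females, measured 81.1 FPKM in hippocampus EE replicate 3 and 70.8 FPKM in hippocampus SH replicate 2, but 0.0258 and 0.0745 FPKM in the cortex libraries of the same numbers, so equal numbers do not mark libraries of 1 fetus in these pairs, if the labels hold. In cortex EE replicate 4 the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y were all at 0 FPKM and Xist was at 0.993 FPKM. In the other 13 libraries the Y-linked genes were expressed. With a term for fetal sex the cortex count stayed at 1 gene and the hippocampus count at 0.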
